A study of Mus musculus with 2 samples.

How the data were processed

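5-Hydroxymethylcytosine (5hmC), the oxidation product of 5-methylcytosine made by the TET enzymes, was mapped in mouse embryonic fibroblasts (MEFs) by enrichment and sequencing. Per the labels' protocols, the cells came from C57BL/6 embryos at day 13.5 and were harvested at passage 0 or at passage 5. Genomic DNA was sonicated, fragments carrying 5hmC were captured with a kit-based GLIB precipitation, in which the hydroxymethyl group is glucosylated and tagged with biotin, and Illumina libraries were made from them. There was 1 library at each passage. The assay reports enriched stretches of DNA and not single modified bases.

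The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.7 and MACS 1.4.1 and the mouse build mm9. They do not assign steps to these tools. The alignment settings, the treatment of duplicate reads, the use of an input control and the peak calling threshold are not given in the sources used here. The authors deposited 1 peak list per library, with a chromosome, a start, an end, a running peak name and a score for every peak. The deposited score is the authors' own value for each peak. It is not named in the lists, and its lowest values of 80.0 at passage 0 and 81.5 at passage 5 lie where a p-value cutoff of 1e-08, on a negative log10 scale multiplied by 10, would put them. Scores were used only to rank or filter peaks within 1 list. The last peak on chromosome 1 ended at base 196991879, beyond the last gene of the GRCm38 gene table at hand. Its positions therefore could not be set beside the peaks, and no gene, exon or CpG annotation was used here. Of the planned results, 3 were not run for this reason: the share of peaks by gene feature, the peaks in gene lists and the CpG content of peaks. Regions take the place of genes. Coordinates are given in mm9, counted from 1.

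Read numbers, coverage and mapping rates are not in the peak lists, so the depth of each library is unknown. The number of peaks that a caller finds depends on depth and on enrichment. With 1 library per passage there is no replicate error, and no p-value is given for any difference between passages. Shares carry 95% exact (Clopper-Pearson) binomial intervals, and ratios of peak numbers carry intervals derived from them. These intervals treat peaks as independent and cover counting error only.

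A peak was called shared when it had at least 1 base in common with a peak of the other list. Chance overlap was described by 1000 random placements of the passage 5 peaks. Each peak was placed on its own chromosome between the first and the last peak of both lists, without excluding assembly gaps. In a second set of 1000 placements each peak moved by at most 100 kb, which keeps the regional density. The second set was added after the data were seen. Chromosome lengths were taken as the span between the first start and the last end in both lists. Peaks were counted by their midpoints in windows of 1 Mb on chromosomes 1 to 19 and X. As a reference for the correlation across windows, 100 random subsets of the passage 0 list were drawn, each as long as the passage 5 list, and the passage 5 peaks were placed at random 100 times.

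The alternatives were a score of at least 100, the upper 50% of each list by score, chromosomes 1 to 19 and X only, peaks within 1 kb merged, at least 50% of the shorter peak shared, a distance of up to 500 bases, the highest-scoring passage 0 peaks alone, and windows of 100 kb. The comparisons, these alternatives and the rule for named regions were fixed before the data were examined. The rule names the 5 highest-scoring peaks of each list, the 5 highest-scoring peaks of each list that had no peak in the other, and the 5 windows with the most peaks in each list. Ties were taken in chromosome order. The overlap counts equalled those of bedtools 2.31.1. On simulated lists of 6726 peaks made with 20.00%, 70.00% and 89.99% shared peaks, the script returned those shares. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.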

Results

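The genomic distribution of 5hmC was compared between MEFs at passage 0 and at passage 5, with 1 library each, to examine the mark at an early and a later passage. The passage 0 list held 60157 peaks and the passage 5 list 6726. No 2 peaks within a list overlapped. Peak scores ran from 80 to 3202 at passage 0, with a median of 129, and from 81.5 to 3100 at passage 5, with a median of 117. The read depth behind the lists is unknown.

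Far fewer 5hmC peaks were called at passage 5. The passage 0 list was 8.94 times as long as the passage 5 list (95% counting interval 8.72 to 9.17). Passage 0 peaks covered 56.8 Mb of the genome and passage 5 peaks 3.89 Mb, a ratio of 14.6. Peaks were also narrower at passage 5. Their mean width was 578 bp at passage 5 against 944 bp at passage 0, and the medians were 563 bp and 850 bp. The difference in covered bases therefore combined fewer peaks and shorter peaks. No replicate error is available for these ratios, and a difference in sequencing depth between the libraries would act on both numbers.

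Most of the peaks called at passage 5 lay at sites that were already peaks at passage 0. Of the 6726 passage 5 peaks, 4703 shared at least 1 base with a passage 0 peak, which is 69.9% (95% exact interval 68.8% to 71.0%). When the passage 5 peaks were placed at random on their chromosomes, the median share was 3.81% and the highest of 1000 placements was 4.58%. When each peak moved by no more than 100 kb, the median was 10.7% and the highest 11.8%. The remaining 2023 passage 5 peaks, 30.1% of the list, had no passage 0 peak. In the other direction, 4590 passage 0 peaks had a passage 5 peak, which is 7.63% (7.42% to 7.85%), and 55567 had none. Against only the 6726 highest-scoring passage 0 peaks, the shared part of the passage 5 list was 25%, so most shared sites were not among the top passage 0 peaks.

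Passage 0 peaks that were also called at passage 5 had higher scores and were wider than those that were not. Their median score was 214 (quartiles 140 and 336), against 125 (96.1 and 181) for the peaks called only at passage 0. Their median widths were 1003 bp and 839 bp. The share with a passage 5 peak was 2.38% among the 10% of passage 0 peaks with the lowest scores (2.01% to 2.79%) and 24.4% among the 10% with the highest scores (23.4% to 25.5%). Even in this highest class, 75.6% of the peaks had no counterpart at passage 5. Wider peaks overlap more by chance, and the random placements within 100 kb gave mean shares of 0.757% and 2.57% in these classes. The list was therefore cut into 50 width classes of equal size, a step added after the data were seen. In 49 of them the widest peak was at most 1.51 times as wide as the narrowest, and the last held peaks of 2023 to 21069 bp. In each of the 49, peaks above the class's median score had a passage 5 peak more often than the others, with mean shares of 10.7% and 3.93%.

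**Figure D1:**
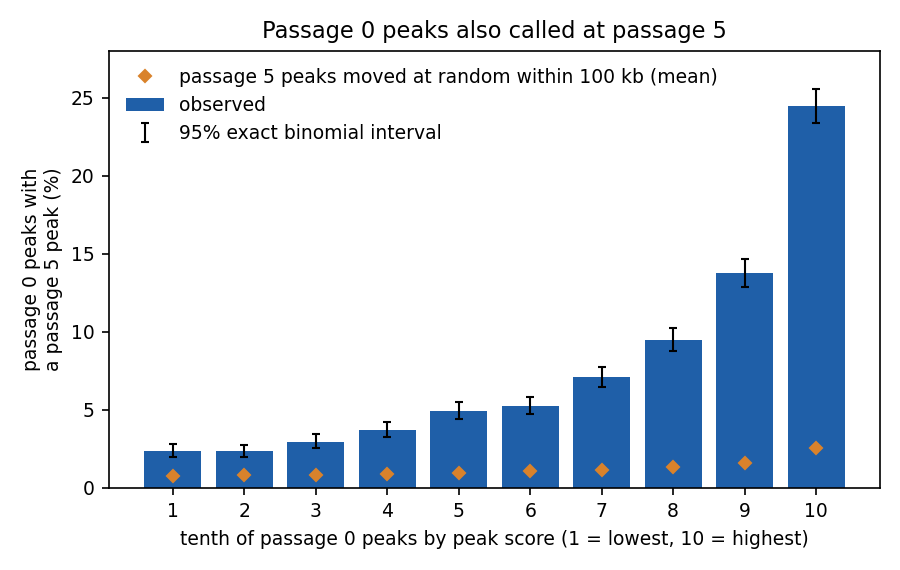
Share of passage 0 peaks that overlap a passage 5 peak (y axis, percent) in 10 classes of equal size by passage 0 peak score (x axis), with 95% exact binomial intervals; diamonds show the mean over 1000 random placements of the passage 5 peaks within 100 kb. The share is 2.38% in the lowest class and 24.4% in the highest.

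The lower number of peaks at passage 5 was seen on all 19 autosomes. The ratio of passage 0 to passage 5 peaks lay between 7.65 on chromosome 11 (6.95 to 8.44) and 10.6 on chromosome 18 (9.27 to 12.2), and it was 8.97 over the autosomes together (8.74 to 9.20). At passage 0 the autosomes held 25.1 peaks per Mb, from 19.5 on chromosome 7 to 32.3 on chromosome 19. At passage 5 they held 2.80 peaks per Mb, from 2.11 on chromosome 14 to 4.01 on chromosome 11.

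The X chromosome carried very few peaks at both passages. It held 65 peaks at passage 0 and 23 at passage 5, or 0.405 and 0.143 per Mb. These densities were 1.62% and 5.13% of the autosomal ones. The X held 0.108% of all peaks at passage 0 (0.0834% to 0.138%) and 0.342% at passage 5 (0.217% to 0.513%). The passage 0 to passage 5 ratio on the X was 2.83 (1.73 to 4.77), below the ratio of every autosome, and these intervals cover counting error only. Part of this came from a cluster near the distal end of the X, between bases 166407584 and 166447018, which held 9 peaks at passage 0 and 10 at passage 5. The covered length in this cluster was 30860 bases at passage 0 and 8741 bases at passage 5. Before 166.4 Mb, the X held 56 peaks at passage 0 and 13 at passage 5, a ratio of 4.31 with an interval of 2.33 to 8.59. That interval reaches into the range of the autosomes but not up to their joint ratio. Only 2 of these 13 passage 5 peaks overlapped a passage 0 peak.

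**Figure D2:**
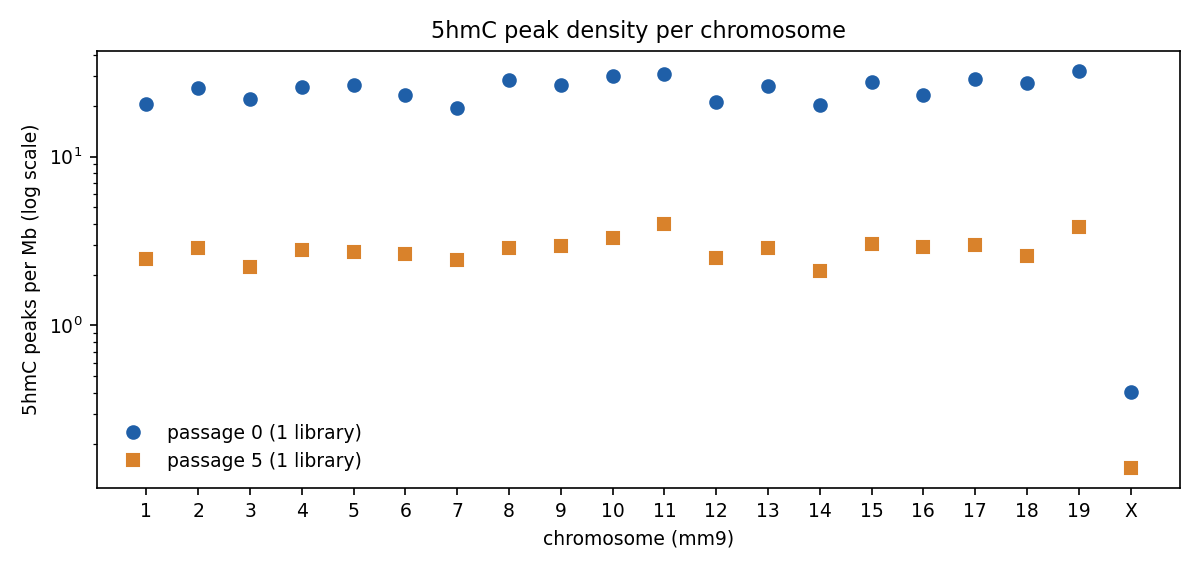
Number of 5hmC peaks per Mb (y axis, log scale) on each chromosome (x axis) at passage 0 (circles) and passage 5 (squares), 1 library each. The autosomes lie at 19.5 to 32.3 peaks per Mb at passage 0 and 2.11 to 4.01 at passage 5, and the X at 0.405 and 0.143.

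The regional layout of 5hmC was similar at both passages. Across 2575 windows of 1 Mb, the numbers of peaks at passage 0 and passage 5 had a Spearman correlation of 0.82 and a Pearson correlation of 0.75. Windows are not independent replicates. Random subsets of the passage 0 peaks, as many as at passage 5, gave Spearman values of 0.88 to 0.90, and randomly placed passage 5 peaks gave 0.11 to 0.21. In windows of 100 kb the Spearman correlation was 0.49. No random subsets or placements were set beside this value. Smaller windows hold fewer peaks, so it cannot be read as weaker agreement at that scale. Peaks were present in 2135 windows at passage 0 and in 1648 at passage 5. Of these, 1628 windows had peaks at both passages, 507 at passage 0 only and 20 at passage 5 only. Another 420 windows had no peak at either passage and also entered the correlations.

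The median window held 15 peaks at passage 0 and 1 at passage 5. The 5 windows with the most peaks at passage 0 held 3 to 9 at passage 5, above the median window. Relative to their passage 0 numbers this was low. On the autosomes together the passage 5 number was 11.2% of the passage 0 number, and each of the 5 windows lay below that. The windows were picked for high passage 0 numbers, which favours such a result. The window at 120 to 121 Mb of chromosome 10 held 149 peaks at passage 0 and 9 at passage 5. On chromosome 8, the window at 49 to 50 Mb held 146 and 7 peaks, and that at 111 to 112 Mb held 127 and 6. On chromosome 2, the window at 166 to 167 Mb held 132 and 5 peaks, and that at 169 to 170 Mb held 131 and 3. At passage 5 other windows led. The window at 3 to 4 Mb of chromosome 11 held 46 peaks at passage 5 against 36 at passage 0, and that at 3 to 4 Mb of chromosome 9 held 20 against 14. The other leading windows had fewer peaks at passage 5: 30 against 125 at 167 to 168 Mb of chromosome 2, 19 against 109 at 117 to 118 Mb of chromosome 11, and 18 against 100 at 134 to 135 Mb of chromosome 4. A higher number of peaks was not always a greater covered length. Between bases 3027029 and 3100128 of chromosome 11, 10 passage 0 peaks covered 68138 bases, and 44 passage 5 peaks covered 34651. Between bases 2999856 and 3038395 of chromosome 9, 14 passage 0 peaks covered 12688 bases and 20 passage 5 peaks covered 15564. Both stretches lie close to the first peaks on their chromosomes and hold very high scores. The best scores were 3202 at passage 0 and 585 at passage 5 on chromosome 11, and 1310 and 2260 on chromosome 9. Without reads, it cannot be told whether these stretches reflect 5hmC or reads that piled up for other reasons.

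**Figure D3:**
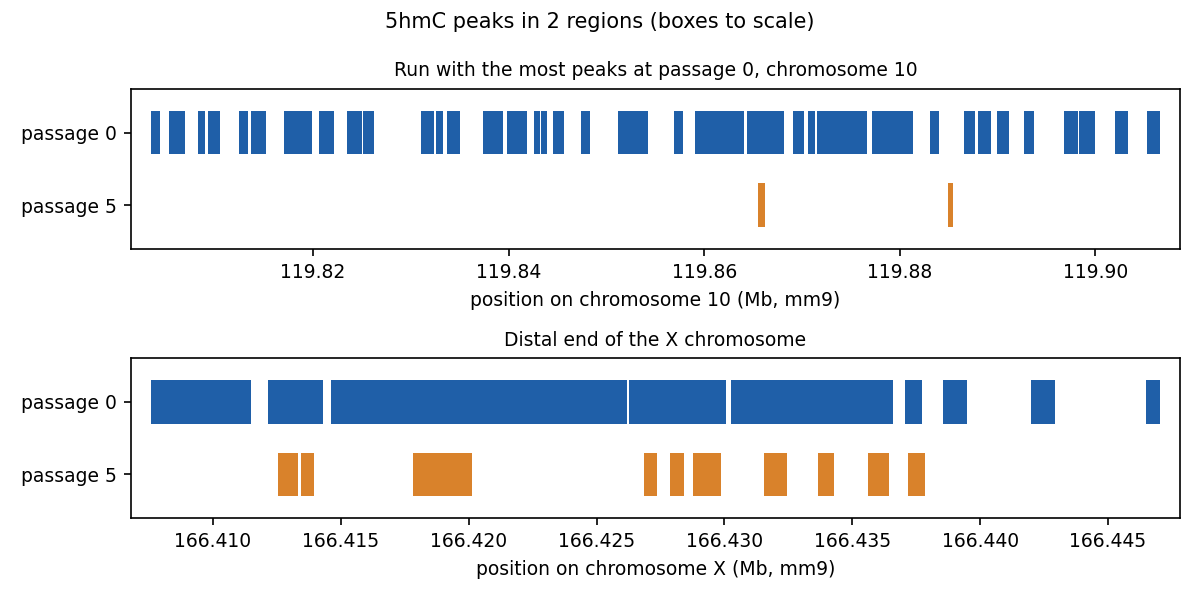
Peaks (boxes, to scale) at passage 0 and passage 5 along chromosome 10 from base 119803451 to 119906559, the run of neighbouring peaks with the most members at passage 0, and along the distal X from base 166407584 to 166447018 (x axes, position in Mb, mm9). The chromosome 10 stretch has 38 peaks at passage 0 and 2 at passage 5, and the X stretch has 9 and 10.

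The highest-scoring peaks of the passage 5 list were shared with passage 0. The 5 highest, all with a score of 3100, lay on chromosome 2 at bases 98502244 to 98503287 and 98506251 to 98507635, on chromosome 9 at 35112656 to 35113322, on chromosome 17 at 39979819 to 39985919, and on the mitochondrial sequence at 1 to 6585. Each overlapped 1 passage 0 peak, with scores of 3100 at all of them except the chromosome 9 site, where it was 2181. At passage 0 the 2 highest scores lay on chromosome 11, at bases 3031534 to 3041136 with 3202 and at 3080794 to 3090835 with 3176. Another 8 peaks were tied at 3100, of which the first in chromosome order were the same sites on chromosome 2 and chromosome 11 at bases 3041183 to 3048915. The exact value 3100 recurred in both lists and may be a ceiling of the score. Whether the 8 tied peaks truly rank below the 2 on chromosome 11 is therefore uncertain. All 5 of these named passage 0 peaks overlapped passage 5 peaks. Without reads or a known input control, it cannot be told whether such scores reflect 5hmC or reads that piled up for other reasons.

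The strongest passage 0 sites without a passage 5 peak were 3914 to 4898 bp wide. The highest lay on chromosome 14 at bases 32476069 to 32480142, with a score of 1494 and the nearest passage 5 peak 48.5 kb away. The next were on chromosome 19 at 44377247 to 44382144 (score 1493), on chromosome 17 at 30600010 to 30604195 (1436), on the X at 166407584 to 166411497 (1424) and on chromosome 15 at 96597753 to 96602259 (1413). The nearest passage 5 peaks to these 4 sites lay 4.13 kb, 142 kb, 1.06 kb and 22.8 kb away.

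Passage 5 peaks without a passage 0 peak had lower scores within their list than shared ones, with medians of 111 and 119. Their share was 33.1% among the 10% of passage 5 peaks with the lowest scores and 12.3% among the 10% with the highest, where it came to 83 peaks. The highest-scoring one lay on chromosome 12 at bases 81954371 to 81955251, with a score of 338 and the nearest passage 0 peak 39.2 kb away. The others were on chromosome 1 at 164821998 to 164822819 (score 332), on chromosome 2 at 18880432 to 18881283 (312), on chromosome 11 at 117215397 to 117216374 (311) and on chromosome 12 at 83255450 to 83256101 (296). Their nearest passage 0 peaks were 2.66 kb, 1.26 kb, 2.27 kb and 14.1 kb away. Without reads, a site outside a list can be said only to have no called peak, not to lack 5hmC.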

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

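The tests on merged peaks and on random false calls were written down before the values they measure were seen. The tests on library depth, on peak borders, on sites under the threshold and on the X chromosome were chosen after the results were seen.

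The Y chromosome, which entered none of the comparisons between chromosomes, held 5 peaks at passage 0 and 2 at passage 5. The 5 lay between bases 2779620 and 2884077, and no expected number for the Y was computed. The highest-scoring one at passage 0 lay at bases 2779620 to 2782949 with a score of 1007, and both passage 5 peaks lay inside it. Each list also had 1 peak on the mitochondrial sequence.

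The first pattern is the 8.94-fold difference in peak number. Different splitting or merging by the caller does not account for it, since the ratio was still 8.0 after peaks within 1 kb were merged. A shallower or less enriched passage 5 library cannot be told apart from less 5hmC at passage 5 for the peaks called only at passage 0, because neither read numbers nor an input control are at hand. The share with a passage 5 peak depended on the score, as lower sensitivity would give, and was 24.4% among the 10% of passage 0 peaks with the highest scores. How far scores fall with depth is unknown, so this value does not decide the question. Loss of 5hmC with passage, the difference the design names, stays open as well and was not tested.

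The second pattern is the 2023 passage 5 peaks without a passage 0 peak. False calls spread evenly within 100 kb do not account for the whole set. Of these peaks, 54.6% lay within 10 kb of a passage 0 peak. The same peaks placed at random within 100 kb, outside passage 0 peaks, gave a median of 47.0% and at most 49.8%. The excess was small, so the test cannot exclude false calls for many of these peaks. False calls that gather in certain regions were not covered by it. Shifted borders account for few of them, since 7.22% lay within 500 bases of a passage 0 peak. Sites just under the passage 0 threshold may explain a part, as the share without a partner was lower among the strongest passage 5 peaks, but it was still 12.3% among the 10% with the highest scores, and this cannot be settled without reads. Sites that gained 5hmC in culture stay open and were not tested.

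The third pattern is the near absence of peaks on the X at both passages. Rows removed after the peaks were numbered are argued against by the running peak numbers, of which 0 were missing. Reads or regions removed before numbering would leave no gap and were not tested. Before 166.4 Mb the X had 1.39% of the autosomal density at passage 0, where none of its peaks reached a score of 320, against 7.81% of the autosomal peaks; at passage 5 the density was 2.9% of the autosomal one and the highest score there was 496. Fewer X copies than autosome copies could lower the signal. With a single X beside paired autosomes, scores falling in proportion to copies would drop from 160 to 80, the lowest score at passage 0. At least 160 was reached by 34.7% of autosomal peaks there, which would stay callable, and by 7.14% of X peaks before 166.4 Mb. At passage 5 the 10% with the highest scores began at 185, against a lowest score of 81.5. The lower X densities argue against fewer copies alone under that assumption. Whether scores follow copies needs read counts, and the labels do not give the sex of the embryos, so a part for fewer copies stays open. The distal cluster of the X was not short of peaks, with 9 at passage 0 and 10 at passage 5 in 0.047 Mb. It was picked for its peaks, so it does not decide the question. The peaks on the Y were not used to infer the sex. Other explanations were not tested.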

How the results depend on the processing

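Of 30 recomputed values for 7 results, 18 stayed within an interval around the reported value, 12 moved beyond it and 0 changed direction. The interval was the exact binomial one for shares and ratios of peak numbers, and the latter rescaled for covered bases. For the score difference it came from binomial limits of both medians, and for the correlation from Fisher's transformation with windows taken as independent. The ratio of peak numbers was 8.40 for peaks with a score of at least 100 and 8.0 with peaks within 1 kb merged. The ratio of covered bases was 16.9 in the upper 50% of each list by score and 15.2 after merging. The share of passage 5 peaks with a passage 0 peak was 68.8% when at least 50% of the shorter peak had to be shared, 72.1% within 500 bases, 65.1% for scores of at least 100 and 25% against the highest-scoring passage 0 peaks alone, where fewer sites were available to overlap. The share of passage 0 peaks with a passage 5 peak was 8.38% within 500 bases. The difference in median passage 0 score between peaks with and without a passage 5 peak, 88.9 as reported, was 80.6 within 500 bases. The Spearman correlation across windows was 0.49 in windows of 100 kb and 0.79 for scores of at least 100. The cause of these shifts was not tested. Alternatives chosen after the data were seen left out the regions around passage 5 peaks with a score of at least 1000, or the distal X. Their values stayed within the intervals. The score rule left out 29 passage 5 peaks, fewer than the 44 between bases 3027029 and 3100128 of chromosome 11. The best passage 5 score in that stretch was 585, so these values do not show the results without it. Taking the upper 50% of each list cannot change the ratio of peak numbers by its construction. Other settings could hardly move a value. Keeping chromosomes 1 to 19 and X removed 6 passage 0 and 3 passage 5 peaks, and leaving out very high scores removed 32 and 29. For the X, the passage 5 number was 35.4% of the passage 0 number, with a wide interval of 21.0% to 57.7%. The count of values that stayed is therefore no measure of robustness. The alternatives for gene features, gene lists and CpG content were not run, because no mm9 annotation or sequence was used here. Unknown depth limits all comparisons of peak number, and there was no replicate to leave out.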

Other observations

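At passage 0, 5hmC peaks formed long runs. Of all passage 0 peaks, 57.4% lay within 5 kb of another one, against 25.7% to 26.8% over 100 random placements. There were 174 runs of at least 10 peaks with gaps of no more than 5 kb, and they held 3.8% of the list. The run with the most peaks, 38, stretched over 103 kb of chromosome 10, from base 119803451 to 119906559, and held 2 passage 5 peaks. The next ones were on chromosome 8 at 11322439 to 11405983, with 34 peaks at passage 0 and 8 at passage 5, on chromosome 3 at 27536879 to 27604299, with 27 and 3, on chromosome 8 at 119801603 to 119868916, with 27 and 1, and on chromosome 11 at 76097057 to 76156799, with 25 and 1. The 174 runs together held 263 passage 5 peaks, 3.91% of that list, but 59 of these lay in 2 runs at dense stretches of chromosomes 9 and 11. The other 172 runs held 3.77% of the passage 0 peaks and 3.07% of the passage 5 peaks outside such stretches (95% exact interval 2.67% to 3.51%, counting error only). Runs were picked for their passage 0 peaks, which by itself raises the passage 0 share, so the lower passage 5 share is no sign of a change. A passage 5 peak was called in 113 of the runs and none in the other 61.

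The number of runs depends on the length of a list, so the passage 5 list was set beside 100 random subsets of the passage 0 list of equal number. These subsets held 14 to 42 runs of at least 3 peaks, and passage 5 held 55, or 49 without the dense stretches on chromosomes 2, 9, 11, 17 and X and the mitochondrial peak, which were chosen after the data were seen. None of the subsets held a run of at least 10 peaks, and passage 5 held 2, on chromosome 11 at bases 3031701 to 3099843 with 44 peaks and on chromosome 9 at 3015106 to 3038380 with 15. Both lie close to the first peaks on their chromosomes and belong to the dense stretches, without which passage 5 held 0 such runs. Of the passage 5 peaks, 16.2% lay within 5 kb of another one, against 9.47% to 11.4% in the subsets. Without the dense stretches the passage 5 value was 15.2%. Part of this is a matter of how calls are split, because 95 passage 0 peaks each held at least 2 passage 5 peaks, up to 13, and a subset of passage 0 peaks cannot hold such pieces. With the passage 5 peaks of 1 passage 0 peak counted once, 1 run of at least 10 peaks was left. The number of runs of at least 3 peaks was then 36, inside the range of the subsets. The share within 5 kb was 13.7%, or 13.2% without the dense stretches, still above the range of the subsets. The subsets were drawn without regard to score, whereas passage 0 peaks with high scores had a passage 5 peak more often. Whether subsets matched on score would give a higher share was not tested.

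One hypothesis is that calls were kept at passage 5 by neighbourhood and not only peak by peak. The test was written down before its value was seen. A passage 0 peak that overlapped a passage 5 peak is called kept here. Among kept peaks whose next peak lay 1 to 10 kb away, 11.9% had a next peak that was also kept (234 of 1973, 95% exact interval 10.5% to 13.4%). When the kept status was shuffled 1000 times among peaks of the same class out of 10 by score and 4 by width, the median was 8.57% and the highest value 11.1%. Other classes were added after the first result. With 100 classes by score and 2 by width within each, finer by score but coarser by width, the highest value was 10.9%, and with 20 by score and 20 by width within each it was 10.8%. Without the pairs in the dense stretches the share was 11.5% (226 of 1965), and the highest shuffled values were 10.5% with 10 by 4 classes and 10.4% with 20 by 20. Score and width of the single peak alone may therefore not account for which calls were kept, though the excess is small and local differences in mappability or copy number were not examined.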
